A study of Rattus norvegicus with 24 samples.

How the data were processed

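Transcripts were measured in 2 muscles of the rat (Rattus norvegicus) at 3 ages. The extraocular muscles (EOM) are the small muscles that move the eye, and the extensor digitorum longus (EDL) is a hindlimb muscle that extends the toes. Per the labels, each muscle was taken at 6, 18 and 30 months, with 4 replicates per group and 24 arrays in all. Per the series' design text, tissue of 4 animals was combined into each RNA sample and the 4 replicates of a group were independent, so p-values measure the spread between pools. Whether the EOM and EDL pools of an age came from the same animals is not given in the sources used here.

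Labelled RNA was hybridised to Affymetrix Rat Genome U34 arrays, which report each transcript by a probe set, a group of short probes summarised into 1 value. The deposited values are linear intensities, 1 per probe set and array, which the authors computed with Affymetrix Microarray Suite 5.0, per the series' design text and the submitters' processing notes. The mean over all probe sets without the top and bottom 2% lay near the same value on all 24 arrays, so the values were taken as already scaled between arrays. The sample labels name a pair of dyes while the design text describes a biotin and streptavidin stain, and the table has 1 value per probe set and array, so the arrays were treated as 1-colour. The design text describes difference calls that had to hold in all pairwise comparisons with an average change above 2. Detection calls and scanner files were not used here.

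Of 8799 probe sets, 59 controls were removed. Among the 8740 others, 7006 had 1 gene symbol in the platform annotation, 308 had several and 1426 had none. Names were used only where a probe set had 1 symbol, and 6994 of 7018 such probe sets, controls included, had an Entrez identifier found in the RefSeq gene table for assembly GRCr8, from which no symbol needed updating. Each value below its own array's 25th percentile was set to that percentile, which lay between 21.4 and 34.5 units, and log2 was taken. A probe set was tested if it exceeded its array's 40th percentile, 53.8 to 83.8 units, on at least 3 of the 4 arrays of at least 1 group, which left 5741 probe sets of 3419 named genes and left out 2999. A fold change therefore understates the difference for transcripts near the floor, and where all arrays of the dimmer groups lay at the floor it is given as a lower bound.

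A means model of the 6 groups was fitted over all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 18 residual degrees of freedom. All groups share 1 platform, and the fit gives them 1 estimate of the spread per probe set. Within groups, however, the median Spearman correlation was 0.873 to 0.94 for EDL arrays and 0.944 to 0.962 for EOM arrays. The shared spread may therefore make p-values too small for EDL and too large for EOM. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the probe sets tested, and a probe set was called at an adjusted p under 0.05. The comparisons were EOM against EDL as the mean over ages and at each age, 30 and 18 against 6 months and 30 against 18 months in each muscle, the age by muscle interactions (the change in EOM minus the change in EDL), and a test of any age effect in each muscle. A gene was represented by its brightest probe set, and other probe sets of a named gene were checked for calls and sign.

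In all, 26 gene lists were fixed before values were seen. Those of the muscle fibre were fast sarcomere, slow and cardiac sarcomere, developmental and extraocular isoforms, calcium handling and excitation-contraction coupling, neuromuscular junction and denervation, and myogenic regulators and growth control. Those of metabolism and cell maintenance were glycolysis and glycogen, oxidative phosphorylation, fatty acid oxidation and TCA cycle, heat shock and protein folding, antioxidant and detoxification, ubiquitin and proteasome, circadian clock, immediate early and handling response, and ribosomal proteins and translation. Those of other cells and tissues were extracellular matrix, antigen presentation and interferon response, macrophages with complement and inflammation, T and B lymphocytes, Schwann cells and nerve, adipocytes, endothelium, smooth muscle and pericytes, erythrocytes, orbital gland and retina, and mast cells. Each was tested with camera in limma, which compares the list with the other genes, at a preset correlation of 0.01 between genes. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance 1 way, were alternatives.

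Genes were named by a rule fixed before values were seen. For the mean over ages, and for 30 and 18 against 6 months in each muscle, these were the 8 genes with the largest rise and the 8 with the largest fall among those called, with arrays of the 2 groups not overlapping (at each age for the mean) and the brighter group above the median of all values, 116.6 units. For 30 against 18 months it took 3 each way, and for the interactions 5 each way. Where none passed, the 3 smallest p-values were taken and given as not passing. Up to 4 members with the smallest p of each list described, and Myh13, Myh3, Myh8, Myh7, Myh4 and Pvalb, were added. Every other gene or probe set named was chosen after its values were seen.

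Replicate numbers come from the sample titles. Deviations from the group means correlated above 0.1 in all 4 same-numbered pairs for 30 against 6 months in EOM (lowest r = 0.141), 18 against 6 months in EOM (0.14), 30 against 18 months in EOM (0.163), 30 against 6 months in EDL (0.123) and EOM against EDL at 6 months (0.134). In these 5 comparisons the numbers were taken as pairing the arrays, as seen in the values and not stated in the labels, and a fit with the replicate number as a block is given where it changes a call or moves a count by over 1.5 times. Arrays of replicates 1 and 2 stood apart from those of replicates 3 and 4, so each comparison was also fitted within each of these sets of 12 arrays, a choice made after the other splits of the arrays had been seen.

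The other alternatives were quantile normalisation, centring each array on its median, no floor, a floor at the 40th percentile, a pseudocount in place of the floor, no filter, a filter at the 60th percentile, eBayes without trend or robust, array weights, only the compared groups in the fit, an approximation of the authors' stated consistency rule on values, a threshold of at least 2-fold, genes in place of probe sets, and leaving out each array in turn. The log2 ratio of 3' to 5' beta-actin signal as a covariate, and leaving out both EDL arrays at 6 months with a high ratio, were added after the data had been seen. The procedure was tested on simulated data in which 67, 67 and 66 probe sets changed 1.5-fold, 2-fold and 4-fold. With 4-fold changes it called 68.2% of those changed in EDL and 89.4% in EOM at 30 against 6 months, 89.4% for EOM against EDL and 57.6% for the interaction, and with 2-fold changes 37.3%, 28.4%, 86.6% and 16.4%. With 1.5-fold changes it called 4.5%, 7.5%, 55.2% and 3%. Of its calls, 5.2%, 11.7%, 6.7% and 3.8% were false. The simulated errors were independent and normal, with 1 spread per probe set for all groups. They held no structure between arrays or genes, so these shares need not hold for the real arrays. Both muscles were given the same spread, so a gap between their shares does not measure a difference in spread. The highest share of identical values between a pair of arrays was 0.48%, so no array was a copy of another.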

Results

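Expression was profiled in EOM and in EDL, a fast muscle, of rats aged 6, 18 and 30 months. The comparisons ask how the 2 muscles differ and how each changes with age. Each of the 6 groups held 4 arrays, and each array measured RNA pooled from 4 animals. The median signal per array lay between 89.7 and 136.8 arbitrary units, and the brightest probe set between 20943 and 63872. The number of arrays limits the precision. Levels are means ± SD over n = 4 arrays, log2 fold changes carry their standard error (SE), and adjusted p-values come from limma.

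Replicate 1 of EDL at 30 months stood apart, with a median Spearman correlation of 0.873 to its group against 0.915 to 0.962 for the 23 others. The ratio of 3' to 5' beta-actin signal, which rises as RNA degrades, was 2.54 and 3.54 in replicates 1 and 2 of EDL at 6 months. Its mean was 2.19 ± 1.08 in EDL at 6 months, 1.6 ± 0.4 at 18 and 1.67 ± 0.28 at 30 months. In EOM it was 1.42 ± 0.06, 1.31 ± 0.22 and 1.31 ± 0.12. The corresponding Gapdh ratio stayed between 0.99 and 1.66 on all arrays.

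Among the genes named, Myh13 and Myh8, of 2 myosin heavy chains, differed most between the muscles. Myh13 (Entrez gene 29605), the extraocular myosin, averaged 13490 ± 2266, 15630 ± 427 and 15790 ± 3143 units in EOM at 6, 18 and 30 months. In EDL it averaged 87.45 ± 17.7, 99.02 ± 13.6 and 98.3 ± 73.5, a 169-fold difference (log2 SE 0.20, adjusted p = 3.92e-19). Myh8 (252942), the perinatal myosin, was 152-fold higher in EOM (log2 7.25, SE 0.14, adjusted p = 4.56e-22). Myh3, the embryonic myosin, was 14.9-fold higher and Actc1 (29275), the cardiac alpha-actin, 29.6-fold higher. Of the 14 measured genes of developmental and extraocular isoforms, 7 were higher in EOM, 3 were lower (H19, Des and Igf2) and 4 were not called. The counts adjusted over the list alone were also 7 and 3. The list passed camera as higher (adjusted p = 0.0119, and adjusted p = 0.146 with an estimated correlation).

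All 15 measured genes of the fast sarcomere list were lower in EOM, over all genes and adjusted over the list alone. Among them were Mybpc2 and Mybpc1, myosin-binding proteins (log2 -1.49 and -1.12), Mylk2, the skeletal myosin light chain kinase (-1.36), and Ampd1, muscle AMP deaminase (-1.31). The list passed as lower (adjusted p = 4.21e-08, median -0.63), and not with an estimated correlation (adjusted p = 0.124). Myh4, the fast 2B myosin, was lower by a small amount (log2 -0.34, SE 0.09, adjusted p = 0.0026), as was Pvalb, a calcium buffer of fast fibres (-0.55, SE 0.16, adjusted p = 0.00823). Both calls were lost after quantile normalisation (adjusted p = 0.0982 and 0.108). Myh7, the slow myosin, did not pass (log2 -0.31, SE 0.20, adjusted p = 0.211). Of the 11 slow and cardiac sarcomere genes, 3 were higher (Actc1, Tnnt2 and Tpm3) and 4 lower (Ankrd1, Csrp3, Actn2 and Myl3), with the same counts adjusted over the list alone. The list did not pass (median -0.31, adjusted p = 0.34). Of 25 genes of calcium handling, 5 were higher, with Pln, phospholamban, at log2 2.53, and 12 lower, with Cacng1, a subunit of the muscle calcium channel, at -1.64. Adjusted over the list alone these were 6 and 12, and the list did not pass (median -0.37, adjusted p = 0.0933).

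The other genes with the largest rises in EOM were Ctse (25424), the protease cathepsin E, at 49.4-fold, Spt1 (29229), a salivary secretory protein, at 36.0-fold with all EDL arrays at 18 months at the floor, Tc2n (500707) at 24.3-fold, Ndrg4 (64457) at 21.3-fold and Ak4 (29223), a mitochondrial adenylate kinase. Ak4 lay at the floor on all arrays of the 3 EDL groups and was at least 21.7-fold higher (adjusted p = 1.08e-17). Spt1 varied most: its EOM levels were 5945 ± 7481, 14210 ± 16480 and 229.2 ± 49.4 units at 6, 18 and 30 months. At 18 months replicates 1 and 2 stood at 161.9 and 164.3 against 24663.5 and 31848.7 in replicates 3 and 4. Its log2 difference was 5.17 (SE 0.72, adjusted p = 2.23e-06), in part set by the floor, and 3.97 to 5.69 over the alternatives. The largest falls were Car3 (54232), muscle carbonic anhydrase, at log2 -3.26 (SE 0.32, adjusted p = 1.11e-08), Amhr2 (29530) at -2.90, Ankrd1 (27064), a stretch-responsive sarcomere protein, at -2.85, Abcb4 (24891) at -2.68 and Csrp3 (117505), muscle LIM protein, at -2.63. Aldh1l1 (64392), a folate enzyme, Vtcn1 (295322) and Dhrs7c (287411) followed at -2.46, -2.29 and -2.15. Each of these 16 genes, Myh13, Myh8 and Actc1 included was called in all 40 alternatives.

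**Figure D1:**
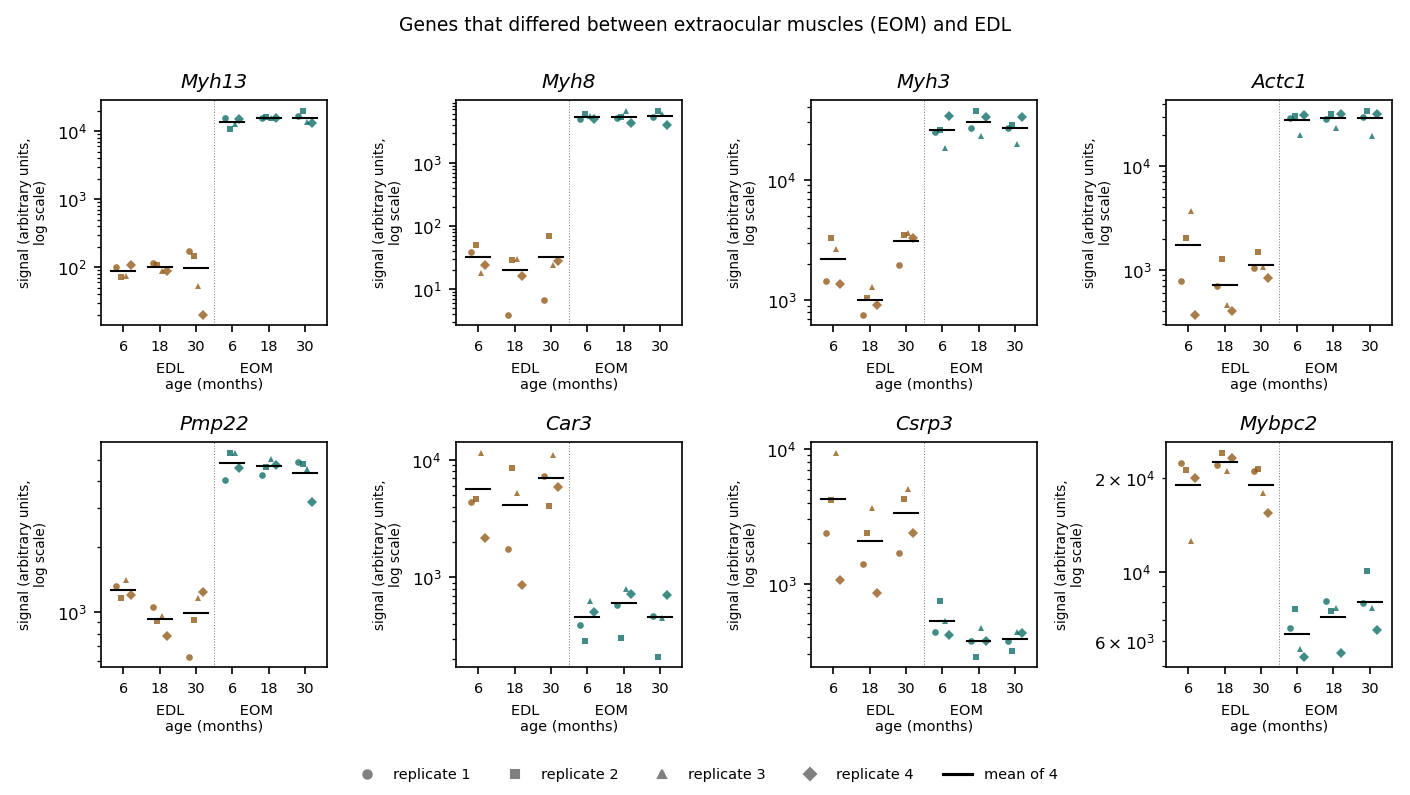
Signal of genes that differed between EOM and EDL on each array (log axis, arbitrary units) in EDL and EOM at 6, 18 and 30 months, with points for arrays shaped by replicate number and lines for the mean of 4. Myh13 averaged 13490 units in EOM and 87.45 in EDL at 6 months.

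Genes of energy metabolism moved in both directions. Among 21 genes of glycolysis and glycogen, 6 were higher in EOM and 14 lower, over all genes and adjusted over the list alone, and the list did not pass (median -0.53, adjusted p = 0.226, direction opposite with fry). The higher genes included Hk1, the main hexokinase of brain and red cells (log2 2.37), Aldoc, the brain aldolase (2.48), Eno1 (1.19) and Pgam1 (1.12). Of 43 genes of fatty acid oxidation and TCA cycle, 17 were higher and 5 lower by both adjustments, with Bdh1, a ketone body enzyme, at 3.32, Ech1 at 1.23 and Slc25a20, the carnitine carrier, at 1.22. That list passed as higher (median 0.09, adjusted p = 0.0391, and adjusted p = 0.152 with an estimated correlation). Of 36 genes of oxidative phosphorylation 4 were higher and 5 lower, or 3 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.797, with a median of -0.03, a mean of 0.03 and a camera direction of lower).

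Among genes that handle oxidants and xenobiotics more were higher in EOM than lower. Of 36 antioxidant and detoxification genes, 18 were higher and 3 lower (18 and 5 adjusted over the list alone), with the glutathione transferases Mgst1 at log2 3.42 and Gsta4 at 1.54, the metallothionein Mt3 at 3.46 and the peroxidase Gpx2 at 1.84. The list passed as higher (adjusted p = 0.00165, and adjusted p = 0.113 with an estimated correlation). Of 35 ubiquitin and proteasome genes 6 were higher and 16 lower by both adjustments, with Trim63, a muscle ubiquitin ligase, at -1.34 and the proteasome subunit Psmc1 at -0.67. The list passed as lower (adjusted p = 0.0119, and adjusted p = 0.205 with an estimated correlation). Of 40 genes of ribosomal proteins and translation 2 were higher and 14 lower by both adjustments, with the muscle elongation factor Eef1a2 at -1.14. That list passed as lower (adjusted p = 0.00241, and adjusted p = 0.224 with an estimated correlation), and no longer after quantile normalisation (adjusted p = 0.0659). Heat shock and protein folding had 6 of 23 genes higher and 4 lower by both adjustments (adjusted p = 0.487). Immediate early and handling response had 5 of 23 higher and 5 lower, or 5 and 6 adjusted over the list alone (adjusted p = 0.797, median 0.15, mean -0.01 and camera direction lower). The circadian clock list had 3 of 9 lower (Bhlhe40, Bhlhe41 and Tef) by both adjustments and did not pass (adjusted p = 0.114).

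Of 19 genes of the neuromuscular junction and denervation, 12 were higher and 3 lower by both adjustments, with the acetylcholine receptor subunits Chrnd at log2 1.43 and Chrne at 1.30, the stress gene Gadd45a at 1.26 and Prkar1a, a regulator of protein kinase A, at 1.13. The list passed as higher (adjusted p = 0.0119, and adjusted p = 0.152 with an estimated correlation). These are means over the ages: 10 genes were higher and 0 lower at 6 months, 8 and 1 at 18, and 3 and 3 at 30. Within replicates 1 and 2 its median was 0.74, 0.73 and -0.03 at these ages, and within replicates 3 and 4 it was 0.65, 0.58 and -0.13. Chrna1 at 30 months stood at 3932 ± 1447 units in EDL and 1771 ± 197 in EOM. Of 28 myogenic regulators and growth control genes, 13 were higher, or 14 adjusted over the list alone, and 5 lower by both. The higher genes included Id2 (log2 1.80), Igf1 (1.54), Ccnd1 (1.06) and Mstn, the growth inhibitor myostatin (2.82-fold). That list passed as higher (adjusted p = 0.0424, and adjusted p = 0.224 with an estimated correlation), and no longer after quantile normalisation (adjusted p = 0.0533).

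Among markers of cells other than muscle fibres, 6 lists passed as higher in EOM beside these gene groups. Of 35 extracellular matrix genes 20 were higher and 5 lower (21 and 5 adjusted over the list alone), with Lum at log2 2.21, Fbln5 at 1.86 and Comp, a cartilage matrix protein, 3.99-fold lower (adjusted p = 0.00486, and adjusted p = 0.381 with an estimated correlation). Its median was 0.77 within replicates 1 and 2 and 0.26 within replicates 3 and 4. By age it was 0.64, 1.20 and 0.85 in the first set and -0.10, 0.66 and 0.01 in the second. Schwann cells and nerve had 12 of 17 higher and 2 lower, with the myelin genes Pmp22 at 2.14 and Mbp at 2.71, S100b at 3.07 and the neurofilament gene Nefm at 3.06 (adjusted p = 0.00125, and adjusted p = 0.152 with an estimated correlation). Adipocytes had 8 of 14 higher and 1 lower (Me1), with the lipid synthesis genes Fasn at 3.14, Acly at 3.13 and Scd at 2.42 (adjusted p = 0.00324, and adjusted p = 0.113 with an estimated correlation). Among its fat cell genes Cidea stood at 2.44, Pparg at 0.85, Cfd at 0.59, Lipe at 0.32, Fabp4 at 0.07 and Lep at -0.16. Fasn and Scd are also among the lipid-secreting gland markers used below, so the list does not separate fat cells from gland. Smooth muscle and pericytes had 8 of 11 higher and 2 lower (Des and Tpm2), with Cnn1 at 1.68 and Acta2 at 1.44 (adjusted p = 0.0176, and adjusted p = 0.233 with an estimated correlation). Erythrocytes had 3 of 4 higher, Hbb at 1.92, Hbb-b1 at 2.02 and Alas2 at 1.43 (adjusted p = 0.0146, and adjusted p = 0.224 with an estimated correlation). Orbital gland and retina had 7 of 8 higher, with Klk1 at 2.98 and Krt19 at 2.55 (adjusted p = 0.0119, and adjusted p = 0.152 with an estimated correlation).

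Antigen presentation and interferon response had 8 of 21 genes higher, among them Psmb8 at log2 1.32 and RT1-S3 at 0.72 (adjusted p = 0.0592). Macrophages with complement and inflammation had 9 of 21 higher, among them C3 at 1.84 or more, with all EDL arrays at the floor, and Serping1 at 1.33 (adjusted p = 0.0747). T and B lymphocytes had 2 of 7 higher, Cd5 at 0.86 and Cd4 at 0.68 (adjusted p = 0.68), endothelium 2 of 11, Ace at 1.30 and Aqp1 at 0.71 (adjusted p = 0.5), and mast cells 0 of 4 (adjusted p = 0.816). In these lists no gene was lower, and the counts adjusted over each list alone were the same in the lists of this and the preceding paragraph other than extracellular matrix. Of the 26 lists, 14 passed camera at the preset correlation, 0 with an estimated correlation and 20 by fry.

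Over the mean of the ages, 2426 of 5741 probe sets differed between the muscles, 1278 higher and 1148 lower in EOM, and 754 of these differed by at least 2-fold (526 higher, 228 lower). The balance of directions depends on the scaling: 1215 were higher and 1319 lower after quantile normalisation, and 1153 and 1392 with arrays centred on their medians. The 2426 probe sets stand for 1483 of 3419 genes. The counts were 1029 at 6 months, 1343 at 18 and 1103 at 30. Of the probe sets, 415 were higher and 202 lower at all 3 ages, against 10.8 and 2.6 for independent lists. Within replicates 1 and 2 the mean over ages gave 1771 calls, and within replicates 3 and 4 it gave 1727. Centring arrays on their medians moved the median log2 difference of all probe sets at 6 months from -0.04 to -0.14, so small differences are relative to that shift.

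**Figure D2:**
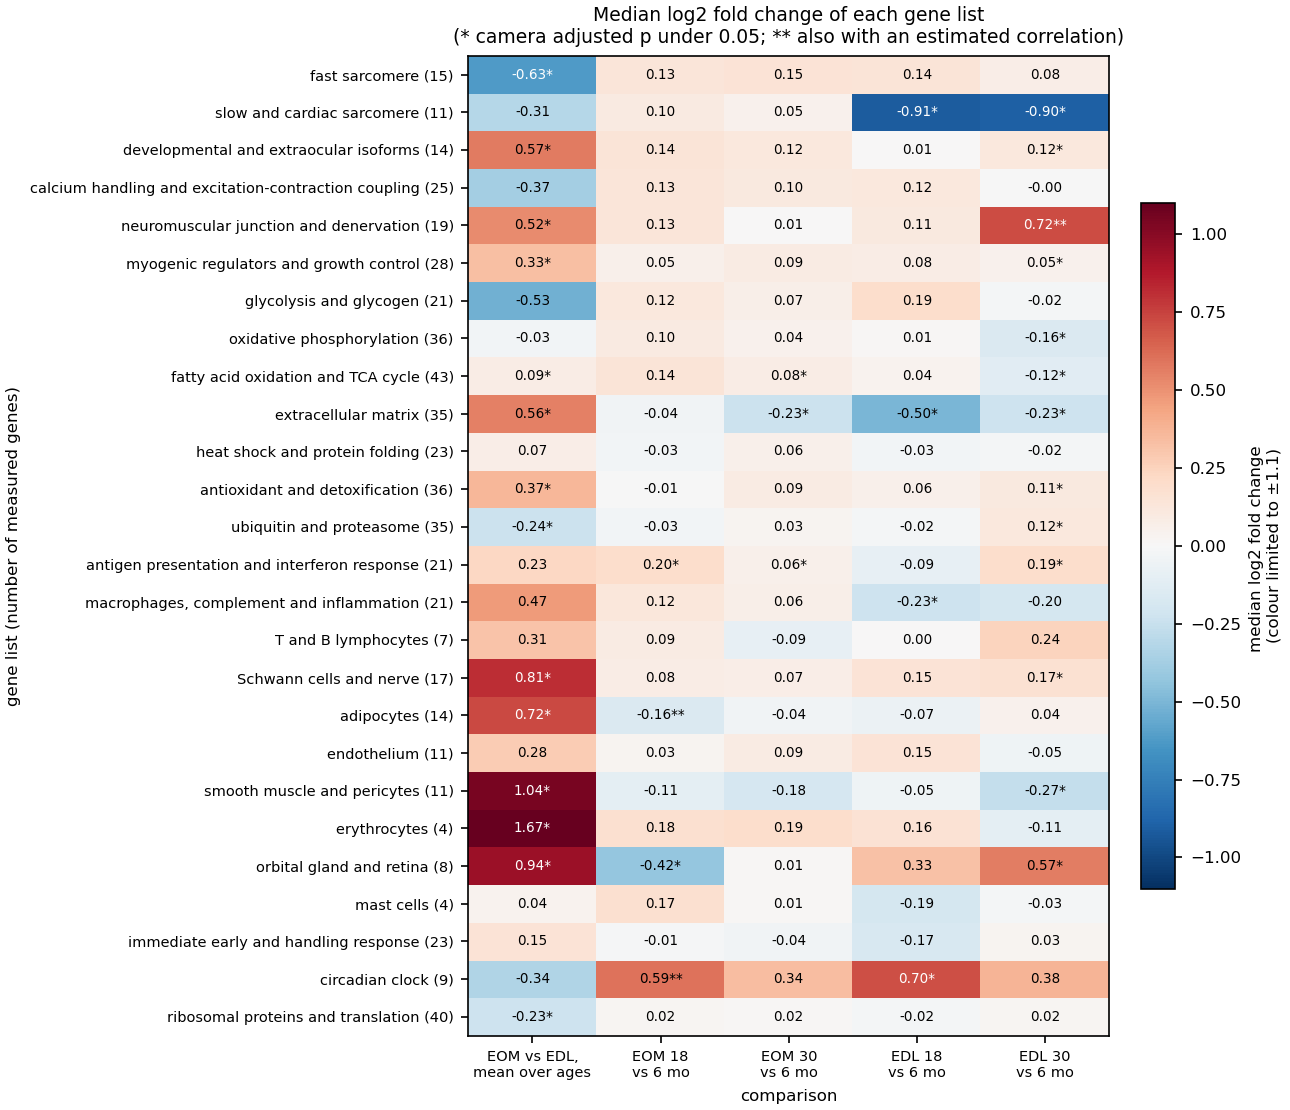
Median log2 fold change of the measured genes of each of 26 lists in 5 comparisons, as colour and number, with 1 star where camera passed and 2 where it also passed with an estimated correlation. The fast sarcomere list stood at -0.63 for EOM against EDL, and the junction list at 0.72 for EDL at 30 against 6 months.

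In EDL, genes of the neuromuscular junction and of the response to lost innervation rose by 30 months. Chrna1 (79557), the acetylcholine receptor alpha subunit, averaged 3932 ± 1447 units at 30 months against 493.6 ± 361 at 6 months, a log2 change of 3.15 (SE 0.30, 8.87-fold, adjusted p = 2.19e-07). Gadd45a (25112), a stress gene, rose 9.67-fold (log2 3.27, SE 0.26, adjusted p = 2.38e-08), Chrnd by log2 2.20 (SE 0.34), Runx1, a transcription factor induced in denervated muscle, by 1.98 (SE 0.35) and Chrnb1 by 1.06 (SE 0.15). Ncam1 (24586), an adhesion molecule of developing muscle, rose by 2.98 (SE 0.59, adjusted p = 0.00529), though its other probe set had the opposite sign and was not called. Of 19 measured genes of the list 7 rose and 0 fell, or 11 and 0 adjusted over the list alone. The list passed camera as higher (median 0.72, adjusted p = 9.18e-12). It alone in this comparison also passed with an estimated correlation (adjusted p = 0.000585). Its median was 0.75 within replicates 1 and 2 and 0.40 within replicates 3 and 4.

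Some regulators of muscle differentiation also rose. Myog (29148), myogenin, rose 9.27-fold (log2 3.21, SE 0.63, adjusted p = 0.00436), Igf2, a growth factor, by log2 2.15 (SE 0.26), Fst, an inhibitor of myostatin, by 2.09 (SE 0.45), Cdkn1a (114851), a cell cycle inhibitor, by 2.68 (SE 0.64, adjusted p = 0.0219) and Myod1 by 1.03 (SE 0.24, adjusted p = 0.0207). These 5 of 28 genes of myogenic regulators and growth control rose and 0 fell by both adjustments (list adjusted p = 0.0272, and adjusted p = 0.294 with an estimated correlation). The call of Cdkn1a was lost without replicate 1 or 2 at 6 months or replicate 1, 3 or 4 at 30 months (adjusted p = 0.0525 to 0.105), and that of Myod1 without replicate 2 or 3 at 6 months or 1 or 2 at 30 months (0.072 to 0.0989). Of 14 developmental and extraocular isoforms, Igf2 and Ncam1 rose, or 5 adjusted over the list alone, and the list passed as higher (adjusted p = 0.00368, and adjusted p = 0.0854 with an estimated correlation). With the replicate number as a block Chrng, the fetal acetylcholine receptor subunit, was also called (log2 0.79, adjusted p = 0.0254).

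**Figure D3:**
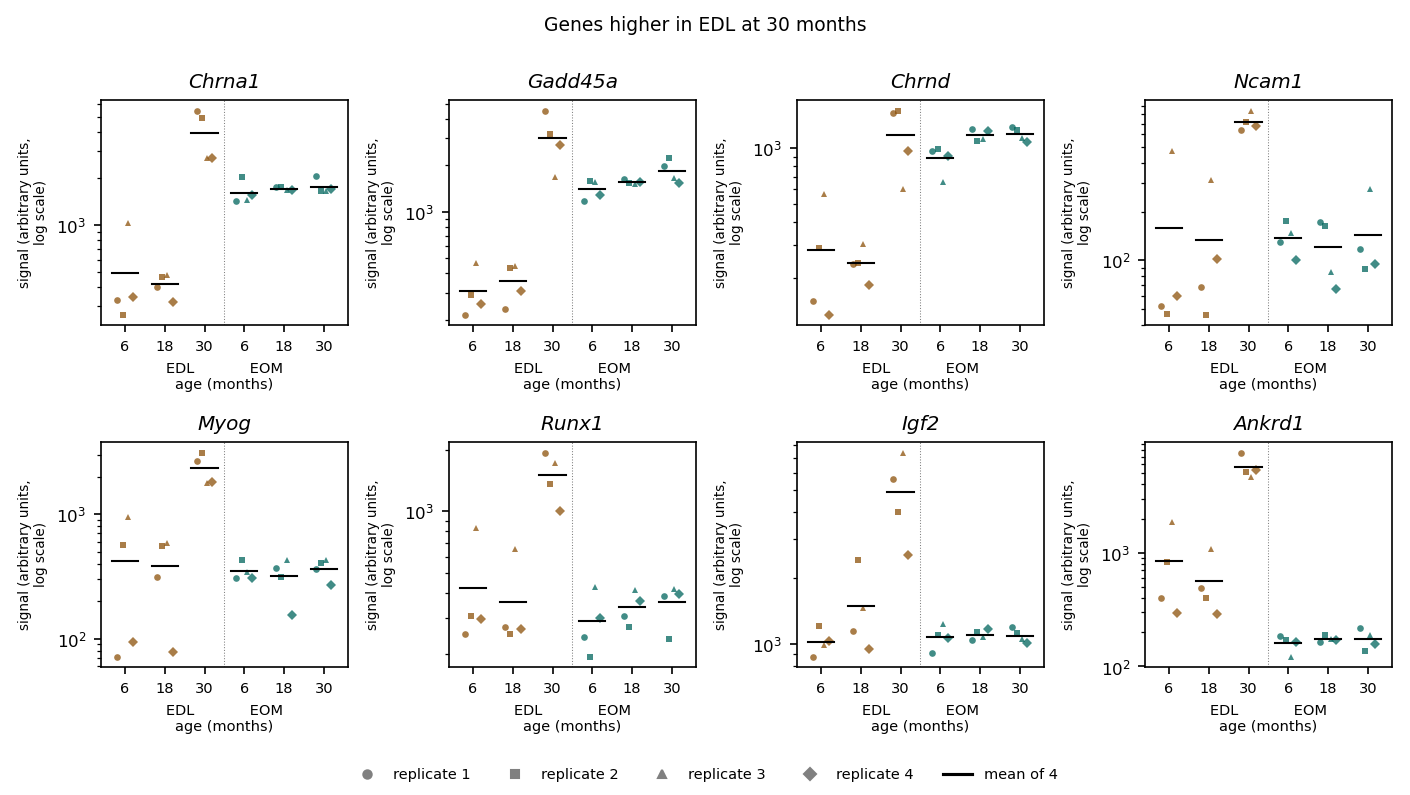
Signal of genes higher in EDL at 30 months on each array (log axis, arbitrary units) in EDL and EOM at 6, 18 and 30 months, with points for arrays shaped by replicate number and lines for the mean of 4. Chrna1 averaged 3932 units in EDL at 30 months against 493.6 at 6 months.

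The largest rise in EDL at 30 months among named genes was Klk1 (24523), a tissue kallikrein, which went from 162.4 ± 171 to 3509 ± 2174 units (30.3-fold, log2 4.92, SE 0.64, adjusted p = 4.73e-05). This value is from a probe set with the suffix for an incomplete set of probes, and the dimmer probe set of Klk1 has the suffix for a gene family. Ankrd1 (27064) went from 842.7 ± 712 to 5698 ± 1322 units (8.59-fold, adjusted p = 4.73e-05) and Polr1a (83581), a subunit of RNA polymerase I, rose 6.30-fold (adjusted p = 0.00245). A probe set without a gene symbol, AF030089UTR#1_at, chosen after its values were seen, rose 51.6-fold (log2 5.69, SE 0.48, adjusted p = 4.81e-08). Klk1 and Krt18, an epithelial keratin (log2 2.61), were the 2 of 8 orbital gland and retina genes that rose, with 0 falling, by both adjustments (list adjusted p = 9.03e-05, and adjusted p = 0.0541 with an estimated correlation). Rises of about 2-fold were called in B2m, the light chain of class I antigen-presenting molecules (log2 1.14, adjusted p = 0.000614), and Ctsl, a lysosomal protease (1.06, adjusted p = 0.000265).

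In EDL 4 collagen genes fell by 30 months. Col1a2 (84352), a chain of type I collagen, went from 5407 ± 1517 to 1359 ± 489 units (log2 -2.03, SE 0.29, adjusted p = 0.000124) and Col3a1 (84032) fell by 1.85 on the log2 scale (SE 0.36, adjusted p = 0.0043). Col1a1 (log2 -1.60, adjusted p = 0.0233) and Col5a2 (-1.56, adjusted p = 0.0407) completed the 4 of 35 extracellular matrix genes that fell, with 0 rising, or 6 and 0 adjusted over the list alone. The call of Col1a1 was lost without replicate 2 or 4 at 6 months or replicate 1 or 2 at 30 months (adjusted p = 0.0648 to 0.141). Col5a2 lost its call without any of 7 arrays (0.0517 to 0.19), namely EDL replicates 2 and 3 at 6 months and 1, 2 and 4 at 30 months, EOM replicate 4 at 6 months and EOM replicate 1 at 18 months. The list passed as lower (adjusted p = 9.03e-05, and adjusted p = 0.294 with an estimated correlation). Pcolce (29569), which helps process procollagen, stood at log2 -1.25 (adjusted p = 0.0157) and lost its call without replicate 4 at 6 months or 1 or 2 at 30 months (0.0539 to 0.0794). The other largest falls were Tfrc (64678), the transferrin receptor (-1.74, adjusted p = 0.00625), Dnaja4 (300721), a co-chaperone (-0.90), and Klhdc3 (363192) (-0.74). Dnaja4 lost its call without replicate 2 at 6 months or 1 at 30 months (0.0556 to 0.0794), and Klhdc3 without replicate 1, 2 or 4 at 6 months or 1 at 30 months (0.0516 to 0.101).

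Other lists passed for EDL at 30 against 6 months. In slow and cardiac sarcomere, Ankrd1 rose and Myl2, a slow myosin light chain, fell (log2 -1.26, adjusted p = 0.0128) and 9 of 11 were not called. Adjusted over the list alone 1 was higher and 6 lower (list lower, adjusted p = 0.0017, and adjusted p = 0.321 with an estimated correlation). Myl2 lost its call without replicate 2 at 6 months or 1 or 3 at 30 months (0.0581 to 0.0746). At 6 months it stood at 23684.9 and 20704.2 units in replicates 2 and 3 against 14738.6 and 10479.4 in replicates 1 and 4. Oxidative phosphorylation had 0 of 36 called either way by both adjustments (lower, median -0.16, adjusted p = 0.000561, and adjusted p = 0.321 with an estimated correlation). Blocked by replicate number its gene Ckmt2 was called (log2 -0.42, adjusted p = 0.006). Fatty acid oxidation and TCA cycle had 0 of 43 called by both adjustments (lower, median -0.12, adjusted p = 0.0272, and adjusted p = 0.195 with an estimated correlation), and did not pass after quantile normalisation (adjusted p = 0.453). Blocked by replicate number its genes Ucp3 (1.11, adjusted p = 0.0248) and Pdk4 (1.47, adjusted p = 0.0319) were called. In antioxidant and detoxification, Gstm2 (1.07, adjusted p = 0.00326) and Gstt1 (1.53, adjusted p = 0.0285) were the 2 of 36 that rose, or 6 adjusted over the list alone, with 0 falling (higher, adjusted p = 0.00399, and adjusted p = 0.131 with an estimated correlation). Gstt1 lost its call without replicate 1, 3 or 4 at 6 months or 1, 2 or 4 at 30 months (0.0579 to 0.0997). Blocked by replicate number Gsta1 was called as well (0.96, adjusted p = 0.0458). In ubiquitin and proteasome, Ctsl was the 1 of 35 that rose by both adjustments (higher, adjusted p = 0.0272, and adjusted p = 0.294 with an estimated correlation).

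In antigen presentation and interferon response, B2m and the class I genes RT1-CE12 (log2 0.77, adjusted p = 0.0133) and RT1-CE16 (0.83, adjusted p = 0.0141) were the 3 of 21 that rose, or 4 adjusted over the list alone, with 0 falling (higher, adjusted p = 0.00201, and adjusted p = 0.294 with an estimated correlation). RT1-CE12 lost its call without replicate 2 at 6 months or 1 or 4 at 30 months (0.0574 to 0.0741), and RT1-CE16 without replicate 1 or 2 at 30 months (0.0773 to 0.0828). In Schwann cells and nerve, Uchl1, a neuronal ubiquitin hydrolase (2.14, adjusted p = 0.00244), and Sncg, a synuclein (1.34, adjusted p = 0.0189), were the 2 of 17 that rose, with 0 falling, by both adjustments (higher, adjusted p = 0.0446, adjusted p = 0.358 with an estimated correlation, and 0.0524 blocked by replicate number). Sncg lost its call without replicate 3 at 6 months or 2, 3 or 4 at 30 months (0.0523 to 0.0855). Smooth muscle and pericytes had 0 of 11 called by both adjustments (lower, median -0.27, adjusted p = 0.0446, adjusted p = 0.358 with an estimated correlation, and 0.0522 blocked). After quantile normalisation this list (adjusted p = 0.0531) and Schwann cells and nerve (0.0613) did not pass, and ribosomal proteins and translation passed as higher (0.00291, against 0.522 before). Macrophages with complement and inflammation (1 of 21 called, adjusted p = 0.748), T and B lymphocytes (0 of 7, adjusted p = 0.754) and endothelium (0 of 11, adjusted p = 0.896) did not pass.

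In all, 107 probe sets changed in EDL between 6 and 30 months, 85 higher and 22 lower, standing for 58 genes (48 and 10), and 87 of them changed by at least 2-fold. With the replicate number as a block the count was 172 (125 higher, 47 lower). Within replicates 1 and 2 it was 180 (150 and 30) and within replicates 3 and 4 it was 5 (5 and 0). Arrays of replicates 1 and 2 set against replicates 3 and 4 of both ages gave 139. The count was 65 without replicate 1 at 30 months, 60 without both 6-month arrays of high actin ratio and 30 when only these groups were fitted. In that last fit Myog, Ncam1, Chrnd, Fst, Tfrc, B2m, Gstm2 and Uchl1 lost their calls (adjusted p = 0.106, 0.0834, 0.0871, 0.241, 0.1, 0.0605, 0.0928 and 0.147), as did Pcolce, Dnaja4, Klhdc3, Myl2, Myod1, Col1a1, Col5a2, Gstt1, RT1-CE12, RT1-CE16 and Sncg (0.121 to 0.301). Without both arrays of high actin ratio Ncam1 (0.202), Cdkn1a (0.487), Uchl1 (0.0803), Klhdc3 (0.274), Myl2 (0.176), Col1a1 (0.0507), RT1-CE12 (0.148), RT1-CE16 (0.133) and Sncg (0.0707) lost theirs. Of 26 lists 13 passed camera, 1 with an estimated correlation and 5 by fry.

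Between 6 and 18 months 4 matrix genes were among the 5 genes that fell in EDL. Col1a2 fell to 997.4 ± 266 units (log2 -2.44, SE 0.29, adjusted p = 8.27e-05). Postn (361945), a matrix protein, stood at -2.07 (SE 0.44, adjusted p = 0.0405), Col3a1 at -1.84 (SE 0.36, adjusted p = 0.0272), Tbc1d2b (315880) at -1.64 (SE 0.26, adjusted p = 0.00388) and Mgp (25333), matrix Gla protein, at -0.96 (SE 0.21, adjusted p = 0.0495). These 5 genes fell and 0 rose among genes represented by their brightest probe sets. Of 35 extracellular matrix genes 4 fell and 0 rose, or 12 and 1 adjusted over the list alone. The list passed as lower (median -0.50, adjusted p = 1.58e-15, and adjusted p = 0.0683 with an estimated correlation). Its median was -0.63 within replicates 1 and 2 and -0.40 within replicates 3 and 4. Col3a1 lost its call without replicate 2 or 3 at 6 months or 1, 2 or 4 at 18 months (0.0635 to 0.12). Postn lost it without any of 14 arrays (0.0526 to 0.162), namely those 5, replicate 1 at 30 months, and all EOM arrays at 6 and 18 months. Mgp lost it without any of 18 arrays (0.0558 to 0.167), namely all EDL arrays at these ages but replicate 4 at 6 months and 3 at 18 months, EDL replicates 1, 2 and 4 at 30 months, EOM replicates 1, 2 and 4 at 6 months, all EOM arrays at 18 months, and EOM replicates 2 and 4 at 30 months. With only these groups fitted Postn (0.526), Col3a1 (0.0769), Tbc1d2b (0.192) and Mgp (0.29) lost their calls, and without both arrays of high actin ratio Postn (0.0563), Tbc1d2b (0.0563) and Mgp (0.186).

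A further 3 lists passed for EDL at 18 against 6 months with 0 genes called over all genes. Slow and cardiac sarcomere was lower (median -0.91, adjusted p = 1.24e-08, and adjusted p = 0.165 with an estimated correlation), with 6 of 11 lower adjusted over the list alone, Myl2 at log2 -0.97, Tnni1, a slow troponin, at -1.22 and Myh7 at -0.91. The 6-month arrays stood apart in these genes, with Tnni1 at 11925 and 11800.8 units in replicates 2 and 3 against 3376 and 1626.8 in replicates 1 and 4. Macrophages with complement and inflammation was lower (median -0.23, adjusted p = 0.0142, and adjusted p = 0.621 with an estimated correlation), with 0 of 21 called adjusted over the list alone. The circadian clock was higher (median 0.71, adjusted p = 0.00141, and adjusted p = 0.0683 with an estimated correlation), with 4 of 9 higher and 1 lower adjusted over the list alone. Dbp, a clock output factor, stood at 1.68 and Bmal1, a core clock factor, at -1.25. The comparison called 16 probe sets, 2 higher and 14 lower. The 2 higher, chosen after their values were seen, were a probe set of Hook1 (log2 1.68) and 1 without a gene name. Within replicates 1 and 2 the count was 47 (33 higher, 14 lower), within replicates 3 and 4 it was 0 by limma, and arrays of replicates 1 and 2 against 3 and 4 gave 318. Leaving out 1 EDL array gave 80 without replicate 4 at 6 months, 4 and 10 without replicates 2 and 3 at 6 months, and 3, 9 and 6 without replicates 1, 2 and 4 at 18 months.

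From 18 to 30 months in EDL, Klk1 rose 19.8-fold (log2 4.31, SE 0.64, adjusted p = 0.000202), Ankrd1 11.2-fold (3.49, SE 0.40, adjusted p = 8.2e-06) and Chrna1 9.09-fold (3.18, SE 0.30, adjusted p = 2.34e-07). Mylk2 (117558) stood at -0.84 (SE 0.20, adjusted p = 0.0217). Mylk2 lost its call without replicate 2 or 4 at 18 months or 1 or 3 at 30 months (0.0503 to 0.117). There were 89 calls, 87 higher and 2 lower, the other lower probe set having no gene name. The count was 61 within replicates 1 and 2 and 2 within replicates 3 and 4, with 74 for arrays of replicates 1 and 2 against 3 and 4. It was 50 without replicate 1 at 30 months, 54 without replicate 4 at 18 months and 53 with only these groups fitted. Any age effect was called for 138 probe sets in EDL, 159 within replicates 1 and 2, 2 within replicates 3 and 4, and 82 without replicate 1 at 30 months. In EOM it was called for 6, or 24 with the replicate number as a block, 0 within replicates 1 and 2 and 1 within replicates 3 and 4. It was 15 without EOM replicate 1 at 30 months and 3 without replicate 2, 1 without replicate 3 at 6 months, and 3, 2, 2 and 3 without replicates 1 to 4 at 18 months.

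In EOM few genes were called for a change with age. Few calls do not show that few genes changed, since 28.4% of simulated 2-fold changes were called in EOM at 30 against 6 months. Between 6 and 18 months C3 (24232), the central complement protein, went from 180 ± 78.2 to 21.2 ± 13.5 units (log2 -2.46, SE 0.36, adjusted p = 0.00248). Car5b (302669), a mitochondrial carbonic anhydrase, stood at -1.89 (SE 0.39, adjusted p = 0.0393), Tc2n at -1.87 (SE 0.39, adjusted p = 0.0387), Xylt2 (64134), a xylosyltransferase, at -1.74 (SE 0.34, adjusted p = 0.0318), Ttc38 (300125) at -1.56 (SE 0.27, adjusted p = 0.0149) and Ppt1 (29411), a lysosomal thioesterase, 2.01-fold lower (log2 SE 0.20, adjusted p = 0.0318). C3 rose again from 18 to 30 months, to 221 ± 84.6 units (log2 2.77, SE 0.36, adjusted p = 0.000323), the 1 probe set called between those ages, while 136 had an unadjusted p under 0.05 against 287 by chance. That count was 3 with the replicate number as a block, 0 within replicates 1 and 2 and 5 within replicates 3 and 4. It was 12 without EOM replicate 1 at 30 months, 3 without EDL replicate 4 at 6 months, and 2 without EDL replicate 2 at 6 months, EDL replicate 4 at 18 months, EDL replicate 2 at 30 months or EOM replicate 1 at 18 months. Both calls of C3 were lost with a floor at the 40th percentile (adjusted p = 0.132 and 0.0667). Without a floor those of Car5b (0.497), Tc2n (0.48), Xylt2 (0.0763) and Ppt1 (0.0645) were lost. Car5b also lost its call with the higher floor (0.142), with a pseudocount (0.0681) and without both EDL arrays of high actin ratio (0.0628), and Tc2n and Xylt2 without a filter (0.0596 and 0.0567). The calls of the 5 other genes were lost without EOM replicate 3 or 4 at 6 months or 2, 3 or 4 at 18 months, and Ttc38 kept its call in every other fit without 1 array (0.0527 to 0.136). Xylt2 (7 fits, 0.0784 to 0.171) and Ppt1 (8 fits, 0.0579 to 0.197) also lost it without replicates 1 and 2 at 6 months, and Ppt1 without replicate 1 at 18 months. Tc2n (12 fits, 0.0505 to 0.263) and Car5b (17 fits, 0.0509 to 0.286) lost it without any 1 of the 8 EOM arrays at these ages. Tc2n also lost it without EDL replicate 1 or 4 at 18 months or 3 or 4 at 30 months, and Car5b without EDL replicate 2 or 4 at 6 months, 1, 3 or 4 at 18 months or any at 30 months.

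Between 6 and 18 months in EOM 10 probe sets were called, 1 higher and 9 lower, and with the replicate number as a block 33 (1 higher, 32 lower). The higher was of Atp2b2, a plasma membrane calcium pump (log2 1.67, adjusted p = 0.0318), chosen after its values were seen. Within replicates 1 and 2, and within replicates 3 and 4, limma called 0 in each, and over all arrays 228 probe sets had an unadjusted p under 0.05 against 287 by chance. The median of the 6 lower genes was -1.62 and -1.83 in these sets. Without EOM replicates 1 to 4 at 6 months the count was 3, 5, 1 and 1, without replicates 1 to 4 at 18 months 3, 1, 1 and 2, and without replicate 1 at 30 months 20. Adipocytes passed as lower (median -0.16, adjusted p = 0.00159, and adjusted p = 0.0421 with an estimated correlation) with 0 of 14 called, or 3 lower adjusted over the list alone. These were Fasn at log2 -1.40, Cidea at -1.29 and Acly at -1.07. Other fat cell genes of the list stood at 0.11 (Lep), 0.18 (Cfd), -0.16 (Fabp4) and -0.09 (Lipe). Among markers chosen after values were seen, the lipid-secreting gland genes Elovl5 and Fabp5 stood at -1.06 and -1.35, and 10 epithelial genes had a median of -0.67. The circadian clock passed as higher (median 0.60, adjusted p = 0.00159, and adjusted p = 0.0421 with an estimated correlation) with 0 of 9 called by both adjustments, Dbp at 1.07, Per2 at 1.01 and Bmal1 at -1.51. With an estimated correlation and the replicate number as a block both gave adjusted p = 0.0827. Antigen presentation and interferon response passed as higher (median 0.20, adjusted p = 0.00159, and adjusted p = 0.428 with an estimated correlation), and orbital gland and retina as lower (median -0.42, adjusted p = 0.0364, adjusted p = 0.422 with an estimated correlation, and 0.0877 blocked), with 0 of 21 and 0 of 8 called by both adjustments.

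Between 6 and 30 months in EOM no gene met the naming rule, and limma called 2 probe sets, both higher, while 132 had an unadjusted p under 0.05, where chance gives 287. These were Atp2b2 (24215), at 109.2 ± 19.6 units at 30 months (log2 1.96, SE 0.32, adjusted p = 0.0163), and a probe set without a gene name. Atp2b2 lost its call without EOM replicate 1, 2 or 3 at 6 months or 2 at 30 months (0.0563 to 0.102), where the count was 0, and the count was 1 without replicate 1 or 4 at 30 months. With only these groups fitted the count was 0 and Atp2b2 gave adjusted p = 0.122. Its call also rested on the floor, with log2 2.43 and adjusted p = 1 without a floor, 0.67 and 0.588 with a floor at the 40th percentile, and 1.48 and 0.103 with a pseudocount. Nefm, a neurofilament gene (log2 1.51, SE 0.33, adjusted p = 0.179), and Bglap, osteocalcin (-1.53, SE 0.39, adjusted p = 0.451), did not pass. The extracellular matrix list passed as lower (median -0.24, adjusted p = 3.03e-08, and adjusted p = 0.386 with an estimated correlation) with 0 of 35 called, or 3 lower adjusted over the list alone, Col1a2 at log2 -1.12, Col1a1 at -1.47 and Col3a1 at -1.31. Col1a1 was called with the replicate number as a block (adjusted p = 0.0236). Fatty acid oxidation and TCA cycle passed as higher (median 0.08, adjusted p = 0.0363, and adjusted p = 0.386 with an estimated correlation) with 0 of 43 called by both adjustments. Antigen presentation and interferon response passed as higher (median 0.06, adjusted p = 0.0149, and adjusted p = 0.516 with an estimated correlation) with 0 of 21 called, or 1 higher adjusted over the list alone. Fast sarcomere passed with the replicate number as a block (adjusted p = 0.012) and not without it (adjusted p = 0.076, median 0.15, 0 of 15 called). Without EOM replicate 1 at 30 months 1 list passed and without replicate 4 at 6 months 5. The count was 0 within replicates 1 and 2 and 1 within replicates 3 and 4.

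**Figure D4:**
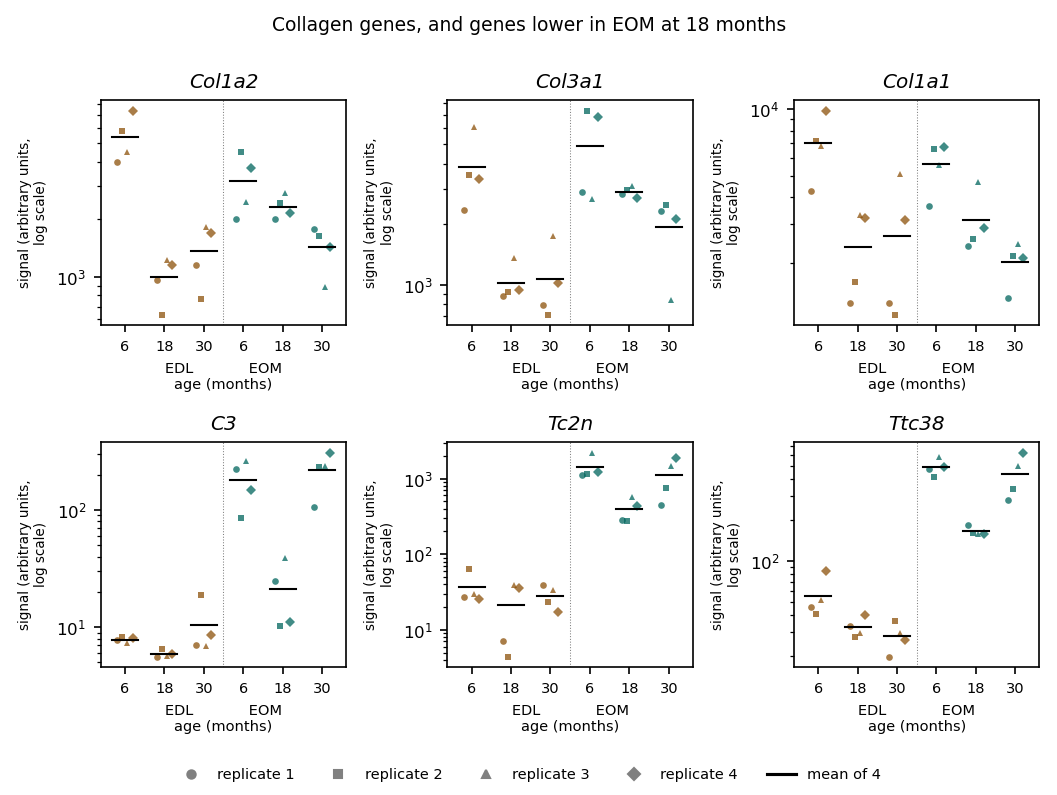
Signal of 3 collagen genes and of 3 genes lower in EOM at 18 months on each array (log axis, arbitrary units), with points for arrays shaped by replicate number and lines for the mean of 4. Col1a2 averaged 5407 units in EDL at 6 months and 997.4 at 18, and C3 in EOM 180 units at 6 months, 21.2 at 18 and 221 at 30.

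The age by muscle interaction tested whether the change from 6 to 30 months differed between the muscles. Chrna1 rose by log2 3.15 in EDL and stood at 0.14 in EOM, a difference of -3.01 (SE 0.42, adjusted p = 0.000321). Gadd45a differed by -2.88 (SE 0.37, adjusted p = 0.000121), Ankrd1 by -2.98 (SE 0.57, adjusted p = 0.015), Igf2 (24483) by -2.12 (SE 0.36, adjusted p = 0.00383) and Ctsl (25697) by -1.41 (SE 0.23, adjusted p = 0.00198). Other probe sets of Gadd45a (3), Igf2 (2) and Ctsl (1) had the same sign but were not called. In EOM at 6 months Chrna1 stood at 1622 ± 286 units and Gadd45a at 1399 ± 200, above their levels in EDL at that age. Of 19 genes of the junction list 3 differed in that direction and 0 in the other, or 6 and 0 adjusted over the list alone. The list passed (median -0.67, adjusted p = 3.49e-11, and adjusted p = 0.00079 with an estimated correlation). Its median was -0.74 within replicates 1 and 2 and -0.39 within replicates 3 and 4. Chrnb1 lost its call without EOM replicate 4 at 30 months (adjusted p = 0.0535) and with only these groups fitted (0.0566), and without both EDL arrays of high actin ratio Chrnb1 (0.0579) and Ankrd1 (0.0757) lost theirs.

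In other lists the interaction at 30 months had few called genes. Orbital gland and retina passed in the same direction (median -0.94, adjusted p = 3.05e-05, and adjusted p = 0.025 with an estimated correlation) with 0 of 8 called, or 2 lower adjusted over the list alone. Fatty acid oxidation and TCA cycle passed in the other direction (median 0.18, adjusted p = 0.000699, and adjusted p = 0.025 with an estimated correlation) with 0 of 43 called, or 1 higher adjusted over the list alone, Fabp3, a fatty acid carrier, at log2 1.02. Slow and cardiac sarcomere (median 0.92, adjusted p = 0.00259, and adjusted p = 0.464 with an estimated correlation) had 0 of 11 called higher and 1 lower (Ankrd1), or 4 and 1 adjusted over the list alone. Oxidative phosphorylation (median 0.20, adjusted p = 0.00025, and adjusted p = 0.426 with an estimated correlation) had 0 of 36 called by both adjustments, and gave adjusted p = 0.0529 after quantile normalisation. Myogenic regulators and growth control (median -0.20, adjusted p = 0.0216, and adjusted p = 0.289 with an estimated correlation) had 0 of 28 called higher and 1 lower, Igf2, or 5 lower adjusted over the list alone. In all 11 probe sets differed, each by a larger rise in EDL. The count was 12 within replicates 1 and 2, 1 within replicates 3 and 4, and 27 without replicate 3 of EDL at 6 months, where 10 lists passed in place of 6.

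For the interaction at 18 against 6 months limma called 0 of 5741 probe sets, while 253 had an unadjusted p under 0.05 against 287 by chance, and 3 were called with array weights. The 3 smallest p-values, which did not pass, were of C3 (log2 -2.59, SE 0.51, adjusted p = 0.123), Col1a2 (2.06, SE 0.41, adjusted p = 0.123) and Ctse (-2.19, SE 0.52, adjusted p = 0.372). C3 lay at the floor on all EDL arrays, so its value is in part set by the floor. The count was 3 without EDL replicate 2 at 18 months and 2 without EOM replicate 2 at 6 months. Slow and cardiac sarcomere (median 1.00, adjusted p = 5.05e-06), extracellular matrix (0.47, adjusted p = 2.77e-07) and antigen presentation and interferon response (0.46, adjusted p = 0.000321) passed as higher and orbital gland and retina (-0.74, adjusted p = 0.0252) as lower. Over all genes 0 were called, and 0, 1 higher, 0 and 1 lower adjusted over each list alone. For each of the 4 the value was adjusted p = 0.374 with an estimated correlation.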

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

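The tests of a single outlying array, of nerve, gland, epithelial, fat and connective tissue were chosen only after the results were seen, and the actin ratio was taken as a covariate after the ratios had been seen. The splits of the samples were set before their results were seen.

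The change from 6 to 30 months differed between the muscles for 11 probe sets by the interaction test, each with the larger rise in EDL. On the log2 scale, EOM minus EDL, the differences were -5.49 for AF030089UTR#1_at, which has no gene name, -3.01 for Chrna1, -2.98 for Ankrd1, -2.88 for Gadd45a, -2.35 for the dimmer probe set of Klk1, -2.26 for S85184_at, also without a name, -2.12 for Igf2, -1.56 for the dimmer probe set of Fst, -1.41 for Ctsl, -1.30 for Slc29a1 and -1.09 for Chrnb1.

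The first pattern is the higher neuromuscular junction list in EDL at 30 months (median log2 0.72). Without replicate 1 at 30 months, the array with the lowest correlation to its group, the median was 0.67, with 10 of 19 genes higher and 0 lower adjusted over the list alone, which argues against that array as the whole cause. With the actin 3' to 5' ratio as a covariate it was 0.64 (adjusted p = 0.000872 with an estimated correlation), which argues against RNA quality, as far as this ratio measures it. More nerve tissue in the older pools cannot be told apart from the pattern: the 7 myelin and Schwann cell markers had a median of 0.17, but 2 SE around their mean of 0.32 reached from -0.24 to 0.88. A response of EDL fibres to age, or to changed innervation, stays open as an untested biological explanation.

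The second pattern is the set of 6 genes lower in EOM at 18 months (median log2 -1.80). In all, 3 relations were tested. Arrays were permuted freely within each age, though same-numbered EOM arrays correlated across ages (lowest r = 0.14). The 12 arrays are therefore not 12 independent units, and the permutation p-values below may be too small. Markers of epithelium followed these genes over the 12 EOM arrays within ages (Pearson r = 0.86, permutation p = 0.00928, adjusted p = 0.0139, and r = 0.6 without the 2 farthest arrays). Spearman rho was 0.78 (permutation p = 0.0161, adjusted p = 0.0242). The epithelial median was -0.67, so a smaller share of epithelium in the 18-month pools is a candidate explanation. These markers include Krt18, Krt19 and Aqp5, which are also in the orbital gland and retina list, so they do not separate gland from other epithelium. For lipid-secreting gland r was higher, at 0.92 (permutation p = 0.00298, adjusted p = 0.00894, and r = 0.79 without the 2 farthest). Its Spearman rho was 0.90 (permutation p = 0.00422, adjusted p = 0.0127). The gland markers' median of -0.28 fell just short of a bound that was set after the results were seen. Among them Fasn, Fabp5 and Elovl5 stood at -1.40, -1.35 and -1.06, and Gpam and Gpd1 at 1.12 and 0.76. Lipid-secreting gland therefore cannot be told apart from epithelium. Orbital fat cannot be told apart either, since its r was 0.44 (permutation p = 0.0839, adjusted p = 0.0839; rho = 0.46, permutation p = 0.124, adjusted p = 0.124; r = 0.30 without the 2 farthest) with a median of -0.12. The secretory gland genes went the other way on average, through replicates 3 and 4 (Spt1 at 5945 units at 6 months and 14210 at 18, Pip at 763.4 and 1740), so whether orbital gland was dissected with some pools, and a change of EOM with age, stay open, untested.

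The third pattern is the lower collagen genes of EDL at 18 months (6 genes, median log2 -1.64). The 16 other fibroblast markers fell too, but less, with a median of -0.36 and a mean of -0.44 (SE 0.13 over the genes). Their mean less 2 SE reached -0.71, short of the -0.82 that the collagen median sets as a bound. That SE measures the spread between genes and not between pools. It therefore cannot decide whether fewer connective tissue cells were the whole cause. Leaving out each 6-month EDL array in turn brought the collagen median no closer to 0 than -1.40, without replicate 3. This argues against 1 outlying array at 6 months, while no 18-month array was left out for this median. With the actin ratio as a covariate the collagen median was -1.71, which argues against RNA quality, as far as this ratio measures it. The collagen median was -1.58 in EDL at 30 months, -0.50 in EOM at 18 and -1.1 in EOM at 30. Both EDL changes are set against the same 6-month EDL arrays, and both EOM changes against the same 6-month EOM arrays, so the values within a muscle are not independent. Lower collagen expression in older muscle may be a biological difference, a hypothesis found and examined in the same data.

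In 13 of 114 groups of 4 arrays a single array lay beyond the limit of Dixon's test. Independent and normal values would give 5.7, or about 1 in 20. The test was run on linear signals, some of them below the floor, so that number is only a rough guide. By signal these were Ctse at 39.8 in EDL at 30 months replicate 2 (others 22.1 to 23.1), Chrna1 at 1032.8 in EDL at 6 months replicate 3 (265.2 to 344.7) and at 2065.5 in EOM at 30 months replicate 1 (1656.8 to 1699), and Klk1 at 6754.7 in EDL at 30 months replicate 2 (2219.9 to 2710.4). Col3a1 stood at 1361.6 in EDL at 18 months replicate 3 (875.3 to 937) and C3 at 19 in EDL at 30 months replicate 2 (6.9 to 8.5). Tc2n stood at 63.6 in EDL at 6 months replicate 2 (25.3 to 29.8) and at 2218.7 in EOM at 6 months replicate 3 (1129.5 to 1218.2), and Atp2b2 at 42.2 in EDL at 6 months replicate 2 (3.9 to 6.9) and 66.5 in EDL at 18 months replicate 1 (4.6 to 5.7). The median Spearman correlation was 0.921 in EDL at 18 months replicate 4 (others 0.931) and 0.947 in EOM at 6 months replicate 2 (0.961 to 0.962), and the actin ratio was 1.26 in EDL at 30 months replicate 4 (1.78 to 1.85).

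Other splits of the arrays into groups of the same sizes were tested. For EOM against EDL chance can be excluded over the mean of the ages, where 1 of 100 splits gave as many calls (real 2426, highest other 60). It can also be excluded at 18 months (1 of 35, 1343 and 2) and 30 months (1 of 35, 1103 and 5). At 6 months 1 of 35 splits gave as many calls (1029 and 40). There only 8 splits part as many pairs (highest other 2), too few to exclude chance on their own. For other results the share was also under 0.05, but leaving out 1 array took the real value to or below the highest other split, so they are not taken as excluding chance. These are the lists of EOM against EDL (2 of 100 splits, real 14, highest other 14; 13 without EDL replicate 1 at any age, EDL replicate 3 at 18 months or EOM replicate 2 at 6 months) and EOM at 18 against 6 (1 of 35, 10 and 3; 1 without EOM replicate 3 or 4 at 6 months or 2 or 3 at 18 months). EOM at 30 against 6 (1 of 35, 2 and 1) gave 0 without EOM replicate 1, 2 or 3 at 6 months or 2 at 30 months. The lists of EDL at 30 against 6 (1 of 35, 13 and 11) numbered 9 without EDL replicate 1 at 6 months or 3 or 4 at 30 months. EDL at 30 against 18 (1 of 35, 89 and 74) gave 50 without EDL replicate 1 at 30 months and 54 without replicate 4 at 18 months, and any age effect in EDL (1 of 100, 138 and 113) gave 82 without the former. The interaction at 30 months (4 of 100, 11 and 41) and any age effect in EOM (2 of 100, 6 and 19) lay below the highest other split with all arrays. In the paired comparisons only 8 splits part as many pairs, too few for a share under 0.05, and the highest other of these was 0 for EOM at 18 and at 30 against 6 and 11 for the lists of EDL at 30 against 6.

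Chance cannot be excluded by the splits for EDL at 30 against 6 months (2 of 35, real 107, highest other 139), although the highest among splits that part as many pairs was 8. Nor can it for EDL at 18 against 6 (3 of 35, 16 and 318) or EOM at 30 against 18 (2 of 35, 1 and 1, or 0 when pairs are parted). The splits with 139 and 318 calls were those of replicates 1 and 2 against 3 and 4, and 318 calls point to a structure of the samples beside age. How the arrays were grouped in the splits with 41 and 19 calls above is not given here. Within replicates 1 and 2 the real counts were 180 and 47, and within replicates 3 and 4 they were 5 and 0. Chance can also not be excluded for the lists of EOM at 30 against 6 (22 of 35 splits, 3 and 9), EOM at 18 against 6 (13 of 35, 4 and 7), EDL at 18 against 6 (21 of 35, 4 and 11), the interaction at 30 months (34 of 100, 6 and 10) and at 18 months (48 of 100, 4 and 10), or for the calls of the latter (100 of 100, 0 and 18).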

How the results depend on the processing

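The alternatives were fixed before the data were examined, other than the tests with the actin ratio as a covariate, without both 6-month EDL arrays of high ratio, of the lists without 1 array, and within replicates 1 and 2 and within replicates 3 and 4, chosen only after the results were seen. Of 268 gene results, 126 were called, 88 of these in every fit outside the 2-fold and consistency rules, and no call reversed direction. By gene results, 25 of 196 lost their call with only the groups compared, 19 of 268 at 2-fold or more, 12 with array weights (8 gained), 10 of 141 under the consistency rule (19 gained), 15 without both high-ratio arrays and 1 with the actin covariate. The replicate block gained 13 and lost 0, among them Klk1 (adjusted p = 0.0057), Myog (0.0447) and Krt18 (0.0447) in the interaction at 30 months and Dbp (0.0306), Bhlhe41 (0.0373), Nr1d2 (0.0203) and Myh3 (0.0495) for EDL at 18 against 6 months. In that fit antigen presentation passed for EOM against EDL (0.044), fast sarcomere for EDL at 18 against 6 (0.0266) and ubiquitin and proteasome for the interaction at 30 months (0.0435), while orbital gland and retina no longer passed for the interaction at 18 months (0.107). With an estimated correlation and the block, the interaction at 30 months gave 0.0684 for orbital gland and retina and 0.0448 for myogenic regulators. Beside these and the blocked values in the report it changed no other call of a gene or list. Of 24 arrays 22 correlated best with arrays of their own number, a hint from the data and not from the design. The cause of the moved values below was not tested, other than that fewer features enter when counting genes or 2-fold changes, and fewer arrays when some are left out.

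Counts of probe sets that moved by more than 1.5 times follow. With quantile normalization EOM at 30 against 6 months gave 1, EOM at 18 against 6 gave 18 and the interaction at 18 months 1. With arrays centred on the median EOM at 18 against 6 gave 17, EOM at 30 against 18 gave 2 and any age effect in EOM 11. With no floor these were 0 for EOM at 30 against 6 (limma, where with the floor 132 had an unadjusted p under 0.05 against 287 by chance), 2 for EOM at 18 against 6 and 1 for any age effect in EOM. A floor at the 40th percentile gave 2 for EOM at 30 against 18, a pseudocount gave 1 for EOM at 30 against 6 and 3 for EOM at 30 against 18, no filter gave 2 for any age effect in EOM, and a filter at the 60th percentile gave 1 for EOM at 30 against 6. eBayes without trend gave 3 for EOM at 30 against 18, 5 for EDL at 18 against 6 and 1 for the interaction at 18 months.

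Array weights gave 4 for EOM at 30 against 6, 44 for EOM at 18 against 6, 3 for EOM at 30 against 18, 4 for EDL at 18 against 6, 3 for the interaction at 18 months, 29 for any age effect in EOM and 89 for EDL. The replicate block gave 33 for EOM at 18 against 6, 3 for EOM at 30 against 18, 172 for EDL at 30 against 6, 35 for EDL at 18 against 6, 147 for EDL at 30 against 18, 34 and 1 for the interactions at 30 and 18 months, 24 for any age effect in EOM and 211 in EDL. Fitting only the groups compared gave 0 for EOM at 30 against 6, 30 for EOM at 18 against 6, 30 for EDL at 30 against 6, 1 for EDL at 18 against 6, 53 for EDL at 30 against 18 and 52 for any age effect in EDL. In the main fit EDL had 16 calls and EOM 10 at 18 against 6 months, so which muscle had more depended on the shared spread. At 30 against 6 months EDL had more in both fits.

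The consistency rule gave 611, 877 and 693 for EOM against EDL at 6, 18 and 30 months, 26 for EOM at 30 against 6, 74 for EOM at 18 against 6, 17 for EOM at 30 against 18 and 55 for EDL at 18 against 6. At least 2-fold changes numbered 754 for the mean over ages and 624, 844 and 670 at 6, 18 and 30 months. Counted as genes there were 1494 for the mean, 662, 848 and 732 at the 3 ages, 1 for EOM at 30 against 6, 2 for EOM at 30 against 18, 58, 3 and 51 for EDL at 30 against 6, 18 against 6 and 30 against 18, 7 for the interaction at 30 months and 77 for any age effect in EDL. The actin covariate gave 3 for EOM at 30 against 18, 27 for EDL at 18 against 6 and 17 for the interaction at 30 months, and EDL at 30 against 6 gave 60 without both high-ratio arrays.

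Leaving out 1 array in turn gave 2301 to 2412 for the mean over ages, 823 to 1082, 1125 to 1396 and 887 to 1165 at 6, 18 and 30 months, 0 to 3 for EOM at 30 against 6, 1 to 20 for EOM at 18 against 6 (highest without EOM replicate 1 at 30 months) and 1 to 12 for EOM at 30 against 18 (the same array). It gave 65 (without EDL replicate 1 at 30 months) to 159 for EDL at 30 against 6, 3 (without EDL replicate 1 at 18 months) to 80 (without EDL replicate 4 at 6 months) for EDL at 18 against 6 and 50 (without EDL replicate 1 at 30 months) to 101 for EDL at 30 against 18. For the interactions it gave 8 to 27 (without EDL replicate 3 at 6 months) at 30 months and 0 to 3 (without EDL replicate 2 at 18 months) at 18 months, and for any age effect 1 to 15 in EOM and 82 to 187 in EDL.

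Lists passing camera with an estimated correlation numbered 0 for EOM against EDL, 0 and 2 for EOM at 30 and 18 against 6 months, 1 and 0 for EDL at 30 and 18 against 6, and 3 and 0 for the interactions at 30 and 18 months. By fry they were 0 and 0 for EOM at 30 and 18 against 6, 5 and 2 for EDL, and 3 and 0 for the interactions. Leaving out 1 array gave 13 to 16 lists for EOM against EDL, 1 to 5 and 3 to 5 for EOM at 30 and 18 against 6, 9 to 13 and 3 to 6 for EDL, and 5 to 10 and 3 to 5 for the interactions. After quantile normalization antioxidant and detoxification passed as higher for EOM at 30 against 6 months (adjusted p = 0.0296), and fatty acid oxidation and TCA cycle for EOM at 18 against 6 (0.0262). For the interaction at 30 months developmental isoforms (0.0333), ubiquitin and proteasome (0.0204) and ribosomal proteins (0.00144) then passed as lower. Beside these and the quantile values in the report no list changed its call. For EDL at 30 against 6, array weights ended the calls of Cdkn1a, Col1a1, Col5a2, Dnaja4, Gstt1, Myl2, Myod1, Pcolce and RT1-CE16 (0.0542 to 0.192), and centring on the median those of Gstt1, Myod1, RT1-CE12 and RT1-CE16 (0.0543 to 0.11). Centring also ended those of Mylk2 (0.0616) and, in the interaction, Chrnb1 (0.156). Gstt1 was lost with quantile normalization (0.131) and the higher floor (0.127), and Col5a2 with no filter (0.0511), without trend (0.0635) and with the actin covariate (0.0573). For EDL at 18 against 6, Col3a1 was lost with array weights (0.165) and without trend (0.0649), and Postn and Mgp in 7 and 11 settings, fits that leave out single arrays or the high-ratio pair not counted. Not run were only the groups compared for the mean over ages, the consistency rule for the mean, the interactions and the tests of any age effect, and the 2-fold rule for the latter. Values under the floor of 21.4 to 34.5 units carry no change. With 4 arrays per group 37.3% of simulated 2-fold changes were called in EDL and 28.4% in EOM at 30 against 6 months. These shares are for errors without structure between arrays.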

Other observations

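No test in this part was chosen to explain a result, and the genes were chosen after their values were seen. Clock genes of both muscles stood at other levels at 18 than at 6 months, though none was called over all genes without the replicate block. Dbp averaged 404.8 ± 86.31 units in EDL at 6 months, 1364 ± 620.8 at 18 and 1085 ± 624.7 at 30, and 433.2 ± 152.4, 904.6 ± 319.4 and 661.8 ± 363.6 in EOM (n = 4 each). Bmal1 averaged 475 ± 127.8, 221.8 ± 113 and 259.4 ± 59.17 in EDL, and 384.8 ± 122.9, 167.4 ± 98.08 and 252.7 ± 102.8 in EOM. The labels give no time of day for the tissue.

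Pip, a protein of secretory glands, varied among EOM arrays as Spt1 did. At 18 months it stood at 13.3, 79.5, 3294.3 and 3572.6 units in replicates 1 to 4, at 6 months at 39.8, 38.4, 2607.1 and 368.4, and at 30 months at 30.3, 33.4, 79.6 and 64.7.

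Slow fibre genes varied among the EDL arrays at 6 months. Csrp3 stood at 2363.9, 4160.9, 9433.3 and 1071.3 units in replicates 1 to 4, and Myh7 at 14895.6, 32182.8, 30415.3 and 7818.1, while in EOM at that age Myh7 averaged 8828 ± 762.3.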
